A study of Mus musculus with 4 samples.

How the data were processed

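Bone marrow cells of 4 male mice were measured by CITE-seq, which reads the mRNA of single cells together with DNA-tagged antibodies bound to their surface. Per the labels' protocols, the marrow was depleted of lineage-positive cells on magnetic columns, LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive) were sorted by flow cytometry, and each animal was loaded separately on the 10x Genomics Single-Cell 3' v3 platform. The deposited table holds counts of unique molecular identifiers (UMIs), not normalized, for 12165 genes, 3 transgene sequences (YFP, iCre and human CD4, so read from their names alone) and 11 antibodies in 20595 barcodes. The submitters' processing notes name Cell Ranger, STAR 2.6.1, R 3.6 and the mm10 build, without saying which step each served. The filters by which barcodes and genes were kept are not given in the sources used here. Every deposited gene had UMIs in at least 21 cells and a mean of at least 0.00675 UMIs per cell. The labels estimate 4000 cells loaded per mouse, whereas the 4 wells hold 6286, 3932, 5150 and 5227 barcodes. All animals belong to 1 group. The barcode suffix gives the well, and each well is 1 animal, but the table does not tie a suffix to a named animal, so the animals are called wells 1 to 4 and n = 4 throughout. The same barcode sequence occurred in 2 wells 31 times, and these were kept as separate cells. Gene identifiers were matched to GENCODE M21 (GRCm38), which gave a symbol for 12153 of 12165, and positions come from that annotation. UMIs of genes that share sequence with a near-identical copy (Hba-a1, Hspa1a and Hspa1b, the histone genes and immunoglobulin variable segments) cannot be assigned with certainty.

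Total gene UMIs were 97109921, 73912461, 88712357 and 90350218 in wells 1 to 4. Cells needed at least 1000 UMIs, 500 detected genes and at most 10% mitochondrial UMIs, which removed 1 barcode and left 20594. Scrublet, run per well at an expected rate of 6%, called 2 cells, which is under 0.5% of the cells, so the caller had not worked and no cell was removed as a doublet. Antibody counts were set on a centred log ratio scale within each cell, and cells were ranked within their well. The TdT reporter comparison takes the 25% of cells highest and the 25% lowest for the human CD4 (hCD4) antibody. The MPP4 gate takes cells above the median for the Flt3 (CD135) antibody and below it for CD150. The ESAM comparison takes MPP4 cells that also lie above the median for hCD4, and sets the third of them with most ESAM antibody against the third with least. The HSC gate takes cells below the median for Flt3 that lie in the third lowest for CD48 and in the third highest for CD150. The MPP2 and MPP3 gates take cells below the median for Flt3 and above it for CD48, with CD150 in the third highest (MPP2) or below the median (MPP3). For the Dntt mRNA comparison every cell was thinned at random to 5000 UMIs, which left out the 563 shallower cells, and cells with a Dntt UMI were set against cells without, with Dntt itself left out. Each antibody was also used alone, the highest 25% of cells against the lowest. Gates are relative ranks and not the gates of a cytometer, so names such as HSC or MPP4 mark a rank in these antibodies only.

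UMIs were summed per well and gate, and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; TMM factors, filterByExpr), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Both gates of a well hold cells of the same animal, so the well was a term of the model, which leaves 3 residual degrees of freedom. This pairing comes from the design. In log2 fold changes ± is an approximate standard error, the fold change divided by the square root of the test's F statistic. It can be too small where a change is large and 1 gate has few UMIs of the gene. In CPM (UMIs scaled to the library total) and in shares ± is the SD over 4 wells. The fits used libraries of 16621000 to 24039000 UMIs for the reporter, 6621200 to 9535000 for ESAM, 13660000 to 32152000 for HSC against MPP4, 3883100 to 10758000 for MPP2 against MPP3 and 3763500 to 25150000 for Dntt mRNA. Those of the YFP fit were the smallest, 289910 to 6715000. On simulated counts with 200 genes changed, the test recovered 94.95% of 1.5-fold and 100% of 2-fold changes for the reporter, 81.44% and 98.97% for ESAM, 87% and 97% for HSC against MPP4, 81.63% and 93% for MPP2 against MPP3, 86% and 97% for Dntt mRNA and 36% and 78.79% for YFP; the share of false calls was at most 5.88%. The simulation gave all genes of a fit the same dispersion, the median of the trend. In the real fits genes differ in their spread between wells and many more were called, so these shares may not hold there. The 19 gene lists were written from general knowledge, as lineage, cell cycle, interferon, stress and contaminating cell type markers. No gene stood in more than 1 list as tested. For naming clusters, Flt3 of the antibody targets was counted with the lymphoid list. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, then again with an estimated correlation and with fry. Of 70 such tests in the 5 planned comparisons, 49 passed with the preset and 18 with the estimated correlation. No stroma gene was tested in any comparison.

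The design, lists, filters and alternatives were set before the data were examined. So was the rule for named genes: the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 30 CPM and the same direction in all 4 wells, up to 4 members per list by smallest p, and always Dntt and the genes of the antibody targets. Values are printed for a part of these genes, those first in each list, and the reversals of all of them under other settings are given. The transgene sequences lie outside that rule and were added after their values were seen. Cells were clustered with Leiden (scanpy 1.11.5, leidenalg 0.10.2, resolution 0.8) on 30 principal components of 2000 variable genes with 15 neighbours. A cluster took a name from at least 3 markers of a list among its 50 leading genes by fold (at least 20 CPM). Set only after the clusters were seen were the conditions that at least 1 marker stand in the first 10 genes and that no other list have more there; the clusters these left unnamed are part of the unnamed share. Alternatives were DESeq2 1.42.0 and its size factors, no filter on low counts, no well term, each well left out, cells thinned to 5000 UMIs (3000 for Dntt mRNA), cells scored S or G2/M left out, all barcodes, narrower gates, antibody counts divided by their total, Gaussian mixture gates, and other cluster resolutions. Chosen after seeing the data were the YFP comparison with its alternatives, log antibody counts without centring, the highest doublet scores left out, the macrophage-like, T/NK-like and neutrophil gene clusters left out, ESAM gates at the same reporter level, and HSC-like or megakaryocyte- and erythroid-primed-like cells left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.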

Results

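LSK cells are the marrow fraction that holds hematopoietic stem cells (HSCs) and multipotent progenitors (MPPs). They were profiled from 4 male mice carrying a pair of reporters of Dntt, the gene of terminal deoxynucleotidyl transferase (TdT), the enzyme that adds untemplated bases at antigen receptor joints. Human CD4 (hCD4) on the cell surface reads the activity of the locus, and iCre, driven by the same gene, switches on YFP from Rosa26, where it stays on in the cell and its progeny. The panel of 11 antibodies read hCD4, ESAM, Flt3 (CD135), the SLAM receptors CD150 and CD48, the chemokine receptor CXCR4, and CD9, CD55, CD41, CD115 and CD105. Wells 1 to 4, 1 animal each, held 6286, 3932, 5150 and 5227 barcodes with medians of 12225.5, 15300.5, 13849.5 and 13989 UMIs and of 3723.5, 4135, 3999.5 and 3978 genes per cell. Median antibody UMIs per cell were 394, 457, 514 and 488, and mitochondrial UMIs made up 1.56%, 1.55%, 1.60% and 1.47%.

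The cells fell into 17 clusters. A HSC-like cluster (Procr, Mllt3, Tgm2, Socs2, Cdkn1c and Ndn among its leading genes) held 14.1% ± 2.57 of the cells, and a lymphoid-primed-like cluster (Ccr9, Dntt, Il12a, Ighm, Satb1 and Notch1) held 11.7% ± 1.88 (SD, n = 4). Megakaryocyte-primed-like cells (Pf4, Treml1, Vwf and Gp5) made up 5.70% ± 1.5 and erythroid-primed-like cells (Car1, Ermap, Rhd and Klf1) 1.64% ± 0.657. Clusters with markers of mature cell types were small. The macrophage-like cluster (C1qa, C1qb, C1qc, Vcam1 and Cd5l) held 1.38% ± 0.324 of the cells, with the progenitor genes Cd34, Kit and Flt3 at 140.7%, 165.9% and 181.0% of their level in the other cells. There were 16 T/NK-like cells (Cd3d, Cd3g and Trbc2), or 0.0766% ± 0.052. The remainder was 39.0% ± 2.00 cycling cells without a lineage name and 26.3% ± 1.96 unnamed cells. The shares moved with the clustering: the HSC-like cluster held 23.6% at resolution 0.5, 9.64% at 1.2 and 24.2% without well 4. The lymphoid-primed-like share was 5.45% without well 2 and 25.1% with cell cycle genes left out of the variable genes, and at resolution 1.2 no cluster took that name. The macrophage-like share was 0.377% without well 2, the erythroid-primed-like share 3.01% without well 1 and the megakaryocyte-primed-like share 8.57% without well 4, and without well 3 or well 4 no cluster took the macrophage-like name.

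Each antibody was set beside the mRNA of its own target, the highest 25% of cells against the lowest. All 11 target genes were higher in the antibody-high cells, in 4 of 4 wells and past the threshold. The log2 fold change was 6.92 ± 0.11 for Dntt with the hCD4 antibody, 4.74 ± 0.08 for Esam, 4.44 ± 0.10 for Cd55, 4.14 ± 0.20 for Slamf1 (CD150) and 4.02 ± 0.08 for Itga2b (CD41). It was 2.51 ± 0.13 for Csf1r (CD115), 2.42 ± 0.05 for Flt3, 2.38 ± 0.04 for Cd48 and 2.05 ± 0.04 for Cd9. The smallest were Eng (CD105), 0.45 ± 0.03, and Cxcr4, 0.16 ± 0.04 (adjusted p = 0.00704), which without well 4 was 0.15 (adjusted p = 0.0519) and with antibody counts divided by their total was −0.58 (adjusted p = 1.3e-07). CXCR4 and CD115 antibody counts had a median of 0 in every well, and 1.0 ± 0 and 0.75 ± 0.5 in their high cells. The high cells had fewer mRNA UMIs (median 11036 against 21842 for CXCR4, 11784 against 21110 for CD115). Most other antibodies were lower in them too, such as CD55 (8.75 against 58.25 for CXCR4, 6.25 against 60.75 for CD115). The hCD4 antibody was higher for both, and CD135 for CD115. At such low counts the centred log ratio ranks cells largely by the other antibodies. These 2 pairs thus say little on whether antibody and mRNA go together. Dntt (ENSMUSG00000025014) lies on chromosome 19 at 41029275 to 41059525 (plus strand, GRCm38), Esam (ENSMUSG00000001946) on chromosome 9 at 37528078 to 37538319 (plus strand) and Flt3 (ENSMUSG00000042817) on chromosome 5 at 147330741 to 147400489 (minus strand).

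**Figure D1:**
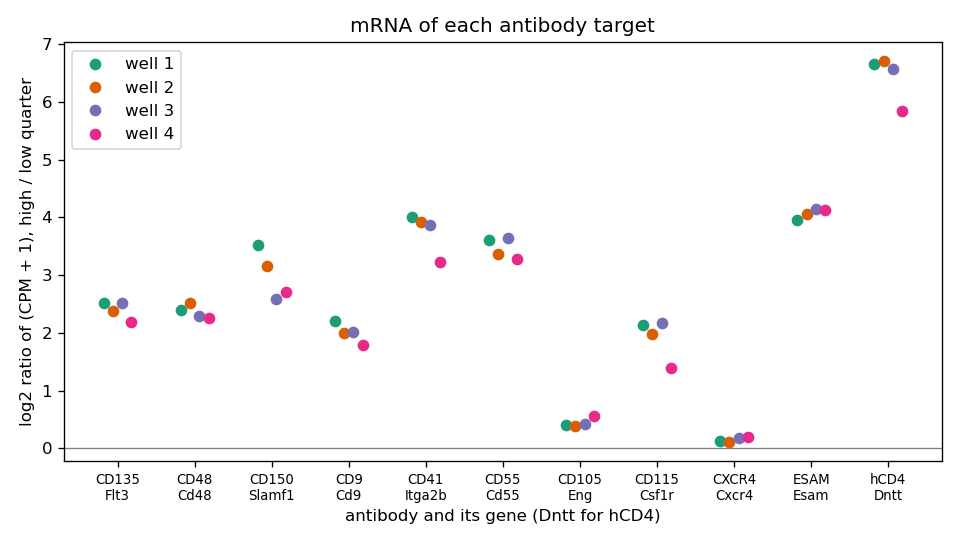
Log2 ratio of (CPM + 1) of each antibody's target gene between the 25% of cells highest and the 25% lowest for that antibody. Each point is 1 well (n = 4) and colours mark the wells. Dntt stands for the hCD4 antibody. All 11 genes lay above 0 in all 4 wells, with fitted log2 fold changes from 0.16 (Cxcr4) to 6.92 (Dntt).

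TdT reporter-high cells carried a lymphoid and dendritic profile and reporter-low cells a stem cell, megakaryocyte and erythroid profile. Dntt was at 265 ± 26.4 CPM in the high cells and 2.17 ± 1.17 in the low cells (log2 fold change 6.92 ± 0.11, adjusted p = 3.6e-16, n = 4 wells). The largest other rises under the rule for named genes were Ighm, the immunoglobulin mu heavy chain constant region (5.13 ± 0.10), the C-type lectin receptor Clec12a (4.31 ± 0.08), Wfdc17 (4.16 ± 0.09), Irf8, a transcription factor of dendritic cells and monocytes (3.88 ± 0.07), and the RNA helicase Ddx4 (3.54 ± 0.07). The largest falls under that rule were Pf4, platelet factor 4 (−5.66 ± 0.18; 7.51 ± 6.24 against 380 ± 92.5 CPM), carbonic anhydrase Car1 of erythroid cells (−5.64 ± 0.13), Apoe (−4.59 ± 0.10), Itga2b (−4.32 ± 0.08), Sdsl (−4.06 ± 0.09) and the vesicular monoamine transporter Slc18a2 (−3.78 ± 0.09). In all, edgeR's test called 6527 of 12161 genes, 3137 higher and 3390 lower in the reporter-high cells, among them 457 up and 755 down by at least 2-fold. The lymphoid-primed-like cluster supplied 39.0% ± 4.37 of the high cells and 0.019% ± 0.038 of the low cells, while HSC-like and megakaryocyte-primed-like cells supplied 35.4% ± 4.71 and 19.5% ± 4.58 of the low cells.

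All 17 tested members of the lymphoid list rose (median log2 fold change 2.70, camera adjusted p = 3.5e-53), with Satb1, a chromatin organizer of lymphocytes (3.20 ± 0.06), and Il12a (2.70 ± 0.04) next to Dntt and Ighm. All 12 dendritic members rose (median 0.53, adjusted p = 1.7e-09). Tcf4 was at 1.05 ± 0.03 and Bst2 at 0.52 ± 0.04. In the stem cell list 21 of 22 fell and none rose (median −2.14, adjusted p = 3.4e-41). Tcf15 was at −4.30 ± 0.12, Pdzk1ip1 at −3.37 ± 0.06 and Angpt1 at −1.37 ± 0.03. All 11 megakaryocyte genes fell (median −4.93, adjusted p = 5.4e-39). Mfsd2b was at −5.62 ± 0.13 and Rab27b at −5.09 ± 0.11. Of 16 erythroid genes 14 fell and 2 rose (median −3.88, adjusted p = 1.6e-26). Gata1, the erythroid and megakaryocyte transcription factor, was at −5.36 ± 0.12 and Aqp1 at −4.80 ± 0.11. These 5 lists kept their calls with an estimated correlation (adjusted p = 0.0267 to 0.0439), as did the genes of the antibody targets (4 rose and 6 fell of 10, median −1.82, adjusted p = 5.8e-06). Flt3 rose by 2.62 ± 0.07 and Cd48 by 1.06 ± 0.04, while Esam fell by 3.81, Cd55 by 3.73 and Cd9 by 2.93 on the log2 scale.

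Other lists were called, but not with an estimated correlation. In the neutrophil and monocyte list 7 rose and 9 fell of 18. The median of the list was −0.15 whereas camera placed it up (adjusted p = 0.0320 and adjusted p = 0.525 with an estimated correlation). Ctss was at 2.06 ± 0.07 and Cebpa at 1.41 ± 0.07 but Ms4a3 at −3.69 ± 0.15. The mast, basophil and eosinophil list had 3 up and 4 down of 7 (median −2.98, adjusted p = 3.3e-04 and adjusted p = 0.111 with an estimated correlation). Cpa3, a mast cell carboxypeptidase, was at −2.98 ± 0.06. S phase genes rose in 17 of 20 (median 0.24) and G2 and M phase genes in 16 of 20 (median 0.25), each at an adjusted p = 0.00649 (adjusted p = 0.549 and adjusted p = 0.551 with an estimated correlation). Gins2 was at 0.43 ± 0.04 and Kif23 at 0.77 ± 0.04. Interferon response genes rose in 10 and fell in 3 of 15 (median 0.33, adjusted p = 0.00649 and adjusted p = 0.520 with an estimated correlation), led by Ifi27l2a (2.23 ± 0.05). Immediate early and heat shock genes rose in 9 and fell in 4 of 14 (median 0.29, adjusted p = 0.0480 and adjusted p = 0.551 with an estimated correlation). Btg2 was at 1.10 ± 0.07. Without well 2 (adjusted p = 0.0848) or well 4 (adjusted p = 0.150) this list was not called, nor was the neutrophil and monocyte list without well 2 (adjusted p = 0.0771). Mitochondrial genes (2 up and 2 down of 9, or 2 up and 0 down adjusted over the list alone, adjusted p = 0.687), macrophage genes (5 of 5 down, adjusted p = 0.135) and endothelial genes (2 up and 2 down of 6, median −0.22 with camera up, adjusted p = 0.247) were not called as lists. Too small to test, the mature B cell list rose in 2 of 2, the T and NK cell list in 2 of 3 (2 up and 1 down adjusted over the list alone, Lck 2.69 ± 0.08) and the mature neutrophil list fell in 2 of 4 (S100a8 −1.53 ± 0.16). Elsewhere in this comparison, adjustment over each list alone gave the same counts.

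The transgene sequences followed the reporter antibody. They are read as reporter transcripts from their names in the table alone, which no source used here describes. YFP rose to 285 ± 9.83 CPM in the high cells from 37.6 ± 14.8 in the low cells (log2 fold change 2.94 ± 0.14, adjusted p = 6.3e-11). Human CD4 was at 6.07 ± 0.619 against 0.0327 ± 0.0408 CPM and iCre at 2.83 ± 1.04 against 0.0461 ± 0.0381. From the lowest to the highest 25% of cells for the hCD4 antibody, Dntt was at 2.25 ± 1.21, 9.25 ± 6.15, 51.7 ± 18.7 and 256 ± 24.5 CPM, as means of 4 wells. In the same order YFP was at 38.9 ± 15.5, 123 ± 25.3, 217 ± 12.9 and 276 ± 6.85 CPM. At 5000 UMIs per cell a Dntt UMI was found in 1.17% ± 0.58 of the lowest and 56.7% ± 4.16 of the highest cells, or 3.23% and 78.6% before thinning. These groups had medians of 12258 and 14050 UMIs, and 209 and 53 shallower cells were left out. Erythroid-primed-like cells, which have no known use of Dntt, gave 1.01% ± 1.28 (5.17% before thinning, median 19673 UMIs). The share in the lowest cells was close to this, but its SD exceeds its mean, so it does not fix a background level. A YFP UMI was found in 9.68% ± 4.13 of the lowest and 72.6% ± 1.60 of the highest cells (16.5% and 94.3% before thinning), against 10.3% ± 1.02 in HSC-like cells (19.8% before thinning, median 9697 UMIs).

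**Figure D2:**
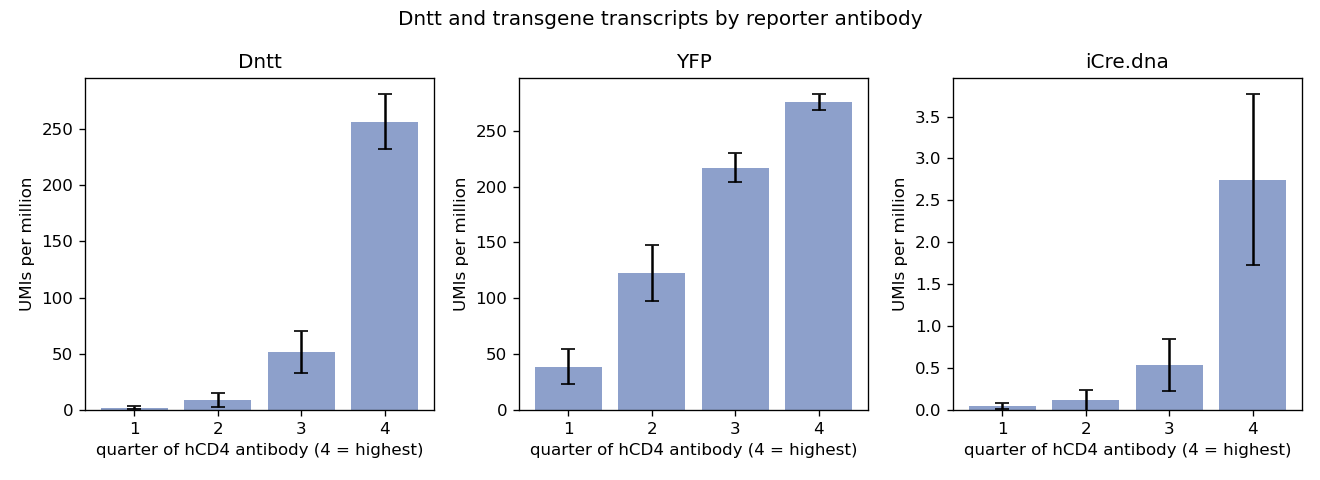
Dntt, YFP and iCre transcripts in CPM (vertical) against the rank of cells for the hCD4 antibody, in 4 equal groups per well (4 = highest). Bars are means and error bars the SD over 4 wells. Mean Dntt went from 2.25 to 256 CPM and mean YFP from 38.9 to 276 CPM between the lowest and the highest group.

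Cells with a Dntt UMI were set against cells with none counted, each thinned to 5000 UMIs. A Dntt UMI was found in 20.2% ± 3.03 of the cells at this depth and in 32.9% before thinning (median 13623.5 UMIs, 563 shallower cells left out), so the group without one also holds cells that carry the transcript. Lymphoid genes were higher in the cells with a Dntt UMI. Stem cell, megakaryocyte and erythroid genes were lower, but these 3 lists lost their calls with an estimated correlation (adjusted p = 0.0535, 0.0747 and 0.0535). In cells with a Dntt UMI Arpp21 (2.49 ± 0.08; 57.6 ± 9.71 against 10.5 ± 5.16 CPM, adjusted p = 5.4e-59), Ighm (1.96 ± 0.04), Cnn3 (1.90 ± 0.07), Clec12a (1.74 ± 0.06), Il12a (1.61 ± 0.04) and Ddx4 (1.58 ± 0.07) rose most under the rule for named genes. Car1 (−4.07 ± 0.11; 3.56 ± 2.59 against 56.5 ± 21 CPM), Apoe (−2.51 ± 0.04), Sdsl (−2.29 ± 0.08), Pf4 (−2.10 ± 0.06), Pdzk1ip1 (−1.87 ± 0.08) and Gng11 (−1.68 ± 0.06) fell most under that rule. The test called 3534 of 12058 genes, 1860 higher and 1674 lower, with 181 up and 367 down by at least 2-fold, in 4024 cells with and 16007 without a Dntt UMI. DESeq2 called 1866 genes, the fit without the pairing by well 1916, and cells thinned to 3000 UMIs gave 2302.

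In this comparison all 16 lymphoid genes rose (median 1.36, adjusted p = 8.3e-58 and adjusted p = 0.0491 with an estimated correlation). Satb1 was at 1.38 ± 0.03 and Notch1 at 1.35 ± 0.05. No other list held its call with an estimated correlation. Stem cell genes fell in 21 of 22 (median −1.18, adjusted p = 4.3e-35 and adjusted p = 0.0535 with an estimated correlation). Angpt1 was at −0.81 ± 0.03 and Hlf at −0.78 ± 0.03. Megakaryocyte genes fell in 11 of 11 (median −2.09, adjusted p = 9.2e-22 and adjusted p = 0.0747 with an estimated correlation). Erythroid genes fell in 12 of 14 and rose in 1 (median −2.19, adjusted p = 2.0e-22 and adjusted p = 0.0535 with an estimated correlation). Zfpm1 was at −1.19 ± 0.07. Dendritic genes rose in 10 of 12 (median 0.28, adjusted p = 1.1e-09 and adjusted p = 0.0535 with an estimated correlation). Irf8 was at 1.37 ± 0.05. G2 and M phase genes rose in 20 of 20 (median 0.44, adjusted p = 3.7e-18 and adjusted p = 0.143 with an estimated correlation). Cenpf was at 0.71 ± 0.04. Neutrophil and monocyte genes fell in 12 and rose in 3 of 18 (14 and 3 adjusted over the list alone, median −0.43, adjusted p = 3.5e-04 and adjusted p = 0.253 with an estimated correlation). Elane was at −3.91 ± 0.19, and 89.9% of all Elane UMIs lay in the neutrophil gene cluster of 95 cells. Mast, basophil and eosinophil genes fell in 5 and rose in 1 of 7 (median −1.76, adjusted p = 7.6e-04 and adjusted p = 0.143 with an estimated correlation). Interferon genes rose in 10 and fell in 2 of 15 (10 and 3 adjusted over the list alone, median 0.26, adjusted p = 2.8e-04 and adjusted p = 0.141 with an estimated correlation). Immediate early and heat shock genes rose in 9 and fell in 3 of 14 (10 and 3 adjusted over the list alone, median 0.24, adjusted p = 3.9e-05 and adjusted p = 0.294 with an estimated correlation). Of the antibody targets 4 rose and 6 fell (median −0.85, adjusted p = 0.0199 and adjusted p = 0.143 with an estimated correlation). Flt3 was at 1.09 ± 0.03 and Esam at −2.12 ± 0.13. The S phase list was not called (5 of 20 up, adjusted p = 0.171, but adjusted p = 0.0263 without well 4). Neither were mitochondrial (2 up and 2 down of 9, or 2 and 3 adjusted over the list alone, adjusted p = 0.532) and endothelial genes (2 up and 2 down of 6, median 0.11 and mean −0.04 with camera up, adjusted p = 0.170). Too small to test were mature B (2 of 2 up), T and NK (2 of 2 up), mature neutrophil (3 of 4 down) and macrophage genes (2 of 4 down).

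Among MPP4 cells positive for the TdT reporter, those with more antibody to ESAM, an adhesion molecule of endothelial and stem cells, had higher stem cell genes and lower lymphoid and G2 and M phase genes. The S phase genes were lower too, without a call for the list with an estimated correlation (adjusted p = 0.0952). The comparison asks whether ESAM divides reporter-positive cells further. Esam mRNA rose from 1.28 ± 0.508 to 9.49 ± 0.747 CPM (2.93 ± 0.21). The largest rises at 30 CPM or more were Rbp1 (1.33 ± 0.06), Apoe (1.31 ± 0.07), Hlf, a transcription factor of stem cells (1.31 ± 0.03; 407 ± 54.5 against 165 ± 34.2 CPM, adjusted p = 7.3e-42, n = 4 wells), Myct1 (1.09 ± 0.05), Mecom (1.08 ± 0.06) and the tetraspanin Cd63 (1.05 ± 0.04). The largest falls under the rule for named genes were Clec12a (−1.55 ± 0.05), Dntt (−1.42 ± 0.04; 94 ± 16.9 against 250 ± 23.4 CPM), Arpp21 (−1.41 ± 0.07), Irf8 (−1.33 ± 0.05), Cnn3 (−1.09 ± 0.06) and Cst7 (−1.02 ± 0.06). Of 11564 genes 4402 were called, 2127 higher (48.3%) and 2275 lower, with 190 up and 71 down by at least 2-fold, in 1829 ESAM-high and 1827 ESAM-low cells. Lymphoid-primed-like cells made up 12.4% ± 3.10 of the ESAM-high and 36.3% ± 3.74 of the ESAM-low cells, unnamed cells 40.4% ± 2.54 and 12.1% ± 3.30, cycling cells without a lineage name 41.8% ± 3.69 and 50.9% ± 2.12, and HSC-like cells 2.92% ± 2.06 and 0%. The hCD4 antibody had a median of 151 UMIs in the ESAM-high and 398 in the ESAM-low cells, and YFP was at 216 ± 8.67 against 287 ± 21.8 CPM (−0.41 ± 0.03). DESeq2 called 2063 genes (36.4% higher), the fit without the pairing by well 2384, cells thinned to 5000 UMIs 1548 (39.7% higher) and cells outside S and G2/M 1207. Gates at the same reporter level gave 2876, log antibody counts without centring 2280 and narrower gates 235.

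**Figure D3:**
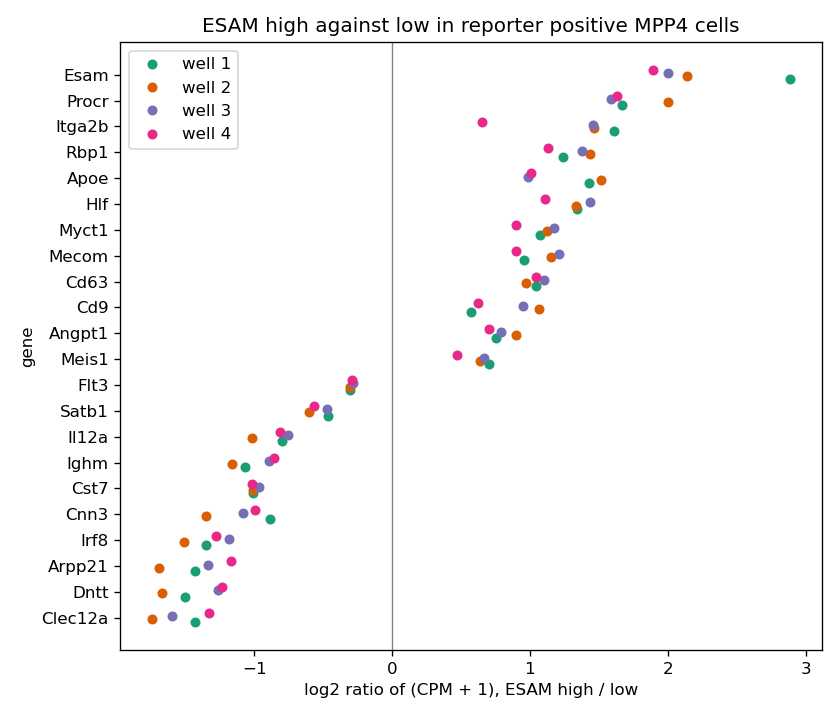
Log2 ratio of (CPM + 1) between ESAM-high and ESAM-low cells of the reporter-positive MPP4 gate for genes with the largest changes and for named stem cell, lymphoid and antibody target genes. Each point is 1 well (n = 4), and colours mark the wells. Fitted log2 fold changes ran from −1.55 (Clec12a) to 2.93 (Esam).

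Stem cell genes rose in 16 of 18 (median 0.82, adjusted p = 3.5e-34 and adjusted p = 0.0447 with an estimated correlation). Procr, the endothelial protein C receptor of HSCs, was at 1.85 ± 0.10, Angpt1 at 0.79 ± 0.04 and Meis1 at 0.63 ± 0.04. With ESAM gates at the same reporter level 14 of 18 rose (median 0.58, adjusted p = 7.2e-30 and adjusted p = 0.0567 with an estimated correlation). All 6 megakaryocyte genes rose (median 1.23, adjusted p = 4.6e-08). Mpl, the thrombopoietin receptor, was at 1.81 ± 0.08 and Pf4 at 1.47 ± 0.15. Lymphoid genes fell in 15 of 17 (median −0.53, adjusted p = 3.9e-32). Ighm was at −0.99 ± 0.04, Il12a at −0.84 ± 0.04 and Satb1 at −0.53 ± 0.03. The ESAM-high cells also had less hCD4 antibody, and the lymphoid list is not given here at the same reporter level. The megakaryocyte and lymphoid lists kept their calls with an estimated correlation (adjusted p = 0.0447 each). All 20 G2 and M phase genes fell (median −0.48, adjusted p = 4.2e-27 and adjusted p = 0.0475 with an estimated correlation). Birc5 was at −0.66 ± 0.04 and Top2a at −0.49 ± 0.03, which in cells outside S and G2/M were 0.10 and 0.11. The phase was scored from the S phase and G2 and M phase lists themselves, so the loss of these falls is no separate result. All 20 S phase genes fell (median −0.40, adjusted p = 6.7e-20 and adjusted p = 0.0952 with an estimated correlation). Gins2 was at −0.63 ± 0.06. Erythroid genes rose in 6 and fell in 2 of 8 (median 0.54, adjusted p = 5.4e-05 and adjusted p = 0.131 with an estimated correlation). Car2 was at 0.80 ± 0.03. Dendritic genes fell in 8 and rose in 1 of 12 (median −0.24, adjusted p = 6.8e-06 and adjusted p = 0.0713 with an estimated correlation). Tcf4 was at −0.28 ± 0.03, but at 0.02 with gates at the same reporter level. In the neutrophil and monocyte list 5 rose and 5 fell of 13 (5 and 6 adjusted over the list alone, median −0.11, camera down with adjusted p = 1.6e-04 and adjusted p = 0.0674 with an estimated correlation). Csf3r was at 0.46 ± 0.06.

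Lists without a call between the ESAM gates were interferon response (7 up and 1 down of 15, adjusted p = 0.299, but adjusted p = 0.0460 without well 4) and immediate early and heat shock (5 up and 4 down of 14, 5 and 5 adjusted over the list alone, adjusted p = 0.357, median 0.009 and mean −0.03 with camera up). Nor was there a call for antibody targets (5 up and 4 down of 9, adjusted p = 0.195), mitochondrial (4 of 9 down, adjusted p = 0.317) or endothelial genes (2 up and 2 down of 5, adjusted p = 0.619). Tie1 was at 1.86 ± 0.14. Too small to test, macrophage genes rose in 4 of 4 (C1qa 1.41 ± 0.24 at 4.47 ± 1.78 CPM), and macrophage-like cells made up 2.35% ± 1.15 of the ESAM-high and 0.72% ± 0.334 of the ESAM-low cells. C1qb turned to −0.22 in thinned cells (edgeR adjusted p = 3.2e-04) and to −0.066 with narrower gates. Mature B cell (1 of 2), T and NK cell (2 of 2, Lck −0.69 ± 0.07) and mast, basophil and eosinophil genes (1 up and 2 down of 4) were also too few. Mature neutrophil genes fell in 2 of 3, S100a9 by 5.72 and S100a8 by 5.71 on the log2 scale, but without well 4 these were 0.39 (adjusted p = 0.246) and 0.88 (adjusted p = 0.0340).

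The HSC gate, low in Flt3 and CD48 and high in CD150, was set against the MPP4 gate, high in Flt3 and low in CD150. HSC-gate cells had higher stem cell and megakaryocyte genes and lower lymphoid and dendritic genes. Erythroid genes were higher too, without a call for the list with an estimated correlation (adjusted p = 0.0849). The largest rises under the rule for named genes were Cavin2 (7.95 ± 0.09; 65.7 ± 18.8 against 0.262 ± 0.0556 CPM, adjusted p = 1.5e-13, n = 4 wells), Pf4 (6.03 ± 0.09), Car1 (4.46 ± 0.33), Apoe (4.02 ± 0.11), Itga2b (3.70 ± 0.07) and Slc18a2 (2.80 ± 0.08). The largest falls under that rule were Dntt (−3.51 ± 0.10; 13.5 ± 4.25 against 150 ± 13.7 CPM), Clec12a (−3.17 ± 0.12), Ighm (−3.04 ± 0.11), Irf8 (−2.90 ± 0.12), Ctsg, cathepsin G of neutrophil granules (−2.82 ± 0.21), and Wfdc17 (−2.73 ± 0.08). The test called 5809 of 12160 genes, 2985 higher and 2824 lower, with 540 up and 401 down by at least 2-fold, in 3642 HSC-gate and 6824 MPP4-gate cells. HSC-like cells made up 40.9% ± 4.33 and megakaryocyte-primed-like cells 24.7% ± 4.16 of the HSC gate, against 4.72% ± 1.24 and 0% of the MPP4 gate, which held 21.6% ± 2.29 lymphoid-primed-like cells. YFP was at 49.9 ± 10.6 CPM in the HSC gate and 239 ± 6.52 in the MPP4 gate.

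Stem cell genes rose in 21 of 22 (median 1.77, adjusted p = 8.3e-45). Tgm2 was at 4.52 ± 0.10, Trpc6 at 4.05 ± 0.09 and Tcf15 at 3.40 ± 0.10. All 11 megakaryocyte genes rose (median 4.32, adjusted p = 4.6e-72). Mfsd2b was at 6.07 ± 0.09 and Vwf, von Willebrand factor, at 5.02 ± 0.10. Lymphoid genes fell in 16 of 17 (median −1.88, adjusted p = 1.3e-32). Satb1 was at −2.32 ± 0.08 and Cd52 at −2.07 ± 0.06. Dendritic genes fell in 10 of 12 (median −0.48, adjusted p = 7.9e-07). Tcf4 was at −0.71 ± 0.03. These 4 lists and the antibody targets (6 up and 4 down of 10, median 1.49, adjusted p = 2.4e-06) held with an estimated correlation (adjusted p = 0.0474 each). Flt3 (−2.04 ± 0.07), Cd48 (−1.44 ± 0.04) and Slamf1 (4.14 ± 0.14) are the mRNAs of the antibodies by which these gates were drawn, while Esam (2.54 ± 0.06), Cd55 (2.83 ± 0.10) and Cd9 (2.52 ± 0.08) are not. Erythroid genes rose in 14 and fell in 1 of 16 (median 3.19, adjusted p = 9.9e-19 and adjusted p = 0.0849 with an estimated correlation). Gata1 was at 5.17 ± 0.16 and Aqp1 at 4.46 ± 0.14.

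Neutrophil and monocyte genes fell in 12 and rose in 2 of 18 in the HSC gate (13 and 2 adjusted over the list alone, median −1.63, adjusted p = 2.5e-06 and adjusted p = 0.415 with an estimated correlation). Mpo, myeloperoxidase, was at −2.20 ± 0.14. G2 and M phase genes fell in 12 of 20 (median −0.19, adjusted p = 0.00835 and adjusted p = 0.617 with an estimated correlation). Kif23 was at −0.75 ± 0.05. S phase genes fell in 10 of 20 (12 adjusted over the list alone) without a call for the list (adjusted p = 0.0769). This list was called without well 1 (adjusted p = 0.0103) or well 4 (adjusted p = 0.0263). Interferon genes fell in 9 and rose in 2 of 15 (median −0.29, adjusted p = 0.00399 and adjusted p = 0.515 with an estimated correlation). Ifi27l2a was at −1.86 ± 0.06. Immediate early and heat shock genes fell in 7 and rose in 3 of 14 (median −0.19, adjusted p = 0.0417 and adjusted p = 0.515 with an estimated correlation). Btg2 was at −0.85 ± 0.07, and this list was not called without well 2 (adjusted p = 0.0968) or well 4 (adjusted p = 0.162). Macrophage genes rose in 5 of 5 (adjusted p = 0.134 as a list, 0.0289 without well 1 and 0.0194 without well 3). C1qc was at 0.94 ± 0.15, while macrophage-like cells made up 0.54% ± 0.208 of the HSC and 1.39% ± 0.512 of the MPP4 gate. The mast, basophil and eosinophil list had 4 up and 3 down of 7 (median 0.76 with camera down, adjusted p = 0.881). The mitochondrial list had 3 of 9 down (adjusted p = 0.472) and the endothelial list 2 up and 3 down of 6 (median 0.12 with camera down, adjusted p = 0.297). Egfl7 was at −1.23 ± 0.03 and Tie1 at 1.65 ± 0.07. Too small to test, the mature B cell list fell in 2 of 2, the T and NK cell list in 2 of 2 and the mature neutrophil list in 1 of 4.

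**Figure D4:**
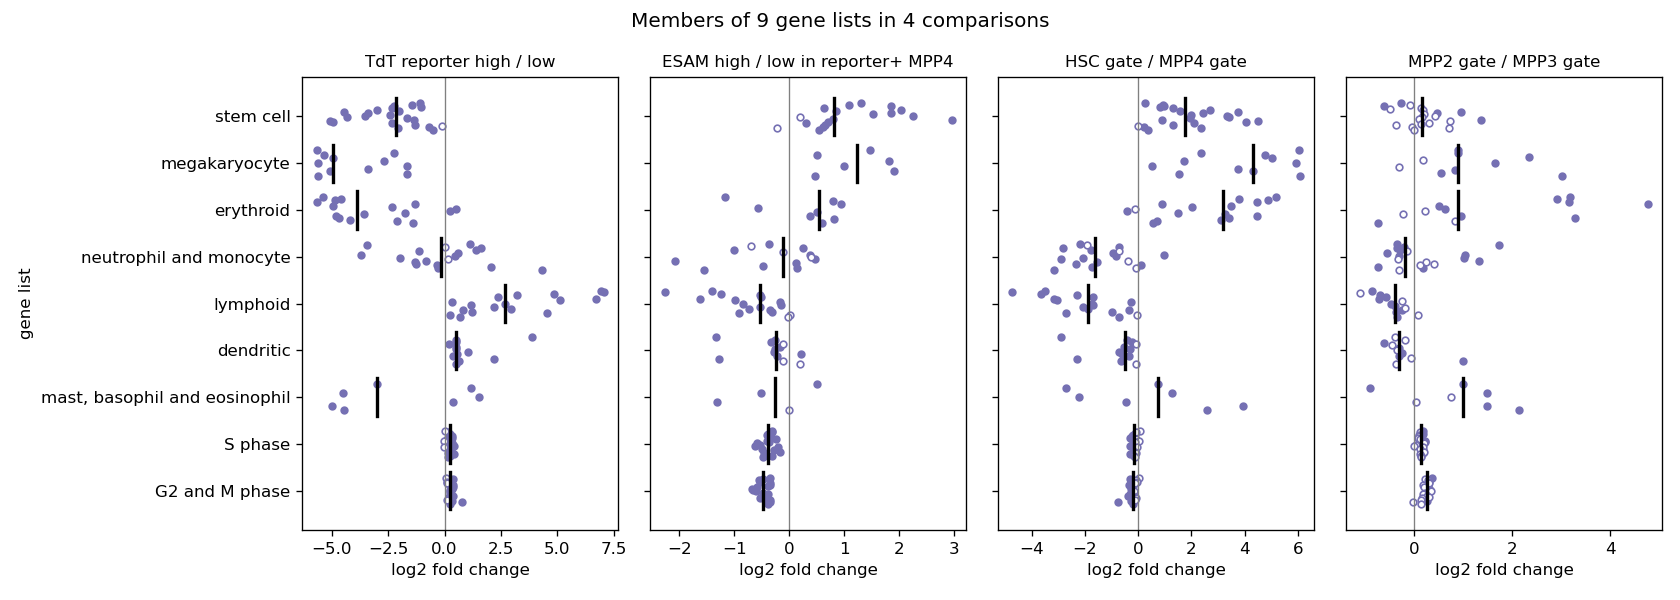
Log2 fold change (horizontal) of each tested member of 9 gene lists (vertical) in 4 comparisons. Filled points passed an adjusted p of 0.05, open points did not, and black bars are medians over members. In reporter-high cells the lymphoid median was 2.70 and the megakaryocyte median −4.93, and in the HSC gate these were −1.88 and 4.32.

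MPP2-gate cells, which were drawn apart from the MPP3 gate by CD150 only, had higher erythroid and megakaryocyte genes. The gates also differed in antibodies not used to draw them, such as hCD4 (median 18.6 ± 11.4 against 41.75 ± 19.7 UMIs). The largest rises under the rule for named genes were Car1 (4.76 ± 0.19; 199 ± 252 against 6.43 ± 5.27 CPM, adjusted p = 1.2e-11, higher in 4 of 4 wells), Apoe (1.94 ± 0.08), Elane, neutrophil elastase (1.73 ± 0.15, with most of its UMIs in the same 95 cells), Cpa3 (0.99 ± 0.09), Itga2b (0.99 ± 0.07) and the transcription factor Gata2 (0.97 ± 0.07). The largest falls under that rule were smaller, namely the chemokine Ccl3 (−0.72 ± 0.11), Ighm (−0.70 ± 0.09), Satb1 (−0.70 ± 0.09), Flt3 (−0.63 ± 0.07), Klf2 (−0.63 ± 0.09) and hexokinase Hk3 (−0.59 ± 0.08). Of 11199 genes 615 were called, 330 higher and 285 lower, with 57 up and 3 down by at least 2-fold, in 870 MPP2 and 1895 MPP3 cells. Megakaryocyte-primed-like cells made up 8.54% ± 3.29 and erythroid-primed-like cells 4.32% ± 5.22 of the MPP2 gate. The count was 187 without well 1, 360 without well 2, 159 with DESeq2, 96 without the pairing by well, 135 with cells thinned to 5000 UMIs, 47 outside S and G2/M and 1 with narrower gates. Antibody counts divided by their total gave 2415 calls (445 of them shared with the 615), no centring 2860 (522 shared) and mixture gates 3863 (578 shared). Under these Elane was −0.57, −1.54 and −4.26, and it was −0.42 without the macrophage-like, T/NK-like and neutrophil gene clusters.

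Erythroid genes rose in 8 and fell in 1 of 12 (10 and 2 adjusted over the list alone, median 0.90, adjusted p = 7.6e-48 and adjusted p = 0.0197 with an estimated correlation). Gata1 was at 3.18 ± 0.18 and Car2 at 0.51 ± 0.03. Klf1 was at 2.91 ± 0.21, but at −0.29 with narrower gates. Megakaryocyte genes rose in 7 of 9 (8 up and 1 down adjusted over the list alone, median 0.90, adjusted p = 1.6e-22 and adjusted p = 0.0197 with an estimated correlation). Mfsd2b was at 3.02 ± 0.21 and Gp5 at 2.34 ± 0.20. Lymphoid genes fell in 9 of 13 (12 adjusted over the list alone, median −0.38, adjusted p = 1.7e-20 and adjusted p = 0.0702 with an estimated correlation). Sell was at −0.38 ± 0.05. Dendritic genes fell in 4 and rose in 1 of 11 (8 and 1 adjusted over the list alone, median −0.30, adjusted p = 6.3e-05 and adjusted p = 0.0702 with an estimated correlation). Runx2 was at −0.30 ± 0.06. Mast, basophil and eosinophil genes rose in 4 and fell in 1 of 7 (5 and 1 adjusted over the list alone, median 0.99, adjusted p = 1.6e-07 and adjusted p = 0.116 with an estimated correlation). Il1rl1 was at 2.15 ± 0.35. S phase genes rose in 6 of 20 (14 adjusted over the list alone, median 0.15, adjusted p = 1.9e-08 and adjusted p = 0.236 with an estimated correlation). G2 and M phase genes rose in 5 of 20 (14 adjusted over the list alone, median 0.27, adjusted p = 1.3e-10 and adjusted p = 0.288 with an estimated correlation). Birc5 was at 0.34 ± 0.07. Of the 10 antibody targets 4 rose and 1 fell (4 and 3 adjusted over the list alone, median 0.07, adjusted p = 1.7e-04 and adjusted p = 0.0702 with an estimated correlation). Slamf1 was at 2.77 ± 0.35 and Cd55 at 1.33 ± 0.15. Stem cell genes rose in 3 and fell in 2 of 20 (6 and 2 adjusted over the list alone, adjusted p = 0.0603, but 0.0268, 0.0192 and 0.0127 without wells 1, 2 and 4, and 0.918 in the other direction without well 3). Pdzk1ip1 was at 0.47 ± 0.08, Hlf at −0.26 ± 0.05 and Procr at −0.62 ± 0.13. Without well 1 Hlf (adjusted p = 0.141), Procr (adjusted p = 0.124), Dntt (−0.86 ± 0.18, then −0.77 with adjusted p = 0.111), Runx2 and Birc5 no longer passed, while without well 4 Dntt was at −1.34 (adjusted p = 2.6e-05). With antibody counts divided by their total Hlf was 0.15 and Procr 0.0087, and without centring they were 0.09 and 0.10.

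Not called between MPP2 and MPP3 were neutrophil and monocyte genes (5 up and 7 down of 18, 5 and 8 adjusted over the list alone, median −0.17 with camera up, adjusted p = 0.970). Mpo was at −0.33 ± 0.04 (0.02 in cells outside S and G2/M) and Ms4a3 at 1.04 ± 0.14 (−0.17 without centring of the antibody counts). Interferon genes (1 of 15 down, median 0.02 with camera down, adjusted p = 0.442) were not called either, with Ifi203 at −0.31 ± 0.05. The same holds for immediate early and heat shock genes (2 up and 3 down of 14, 4 and 4 adjusted over the list alone, adjusted p = 0.738) and mitochondrial genes (0 of 9, adjusted p = 0.607). Too small to test were T and NK cell genes (2 of 3 up, 2 up and 1 down adjusted over the list alone, Cd3d 3.61 ± 0.44 at 4.62 ± 3.64 CPM). T/NK-like cells made up 1.46% ± 1.19 of the MPP2 gate and 0% of the MPP3 gate. Equally few were endothelial (2 of 4 down, 3 adjusted over the list alone), macrophage (0 of 4), mature neutrophil (0 of 3, 1 down adjusted over the list alone) and mature B cell genes (0 of 1, 1 down adjusted over the list alone). Cd48, Eng, Esam, Cxcr4 and Csf1r did not pass the test (log2 fold changes −0.10 ± 0.04, −0.04 ± 0.06, 0.18 ± 0.13, −0.20 ± 0.08 and −0.31 ± 0.27).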

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

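In this part the tests of whole macrophages and of doublets were chosen only after the result was seen, and the test of free RNA was set before.

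A cluster of 276 cells with macrophage genes was found among sorted LSK cells, and its share of 1.86% in well 2 lay far from the 1.15% to 1.26% of the other wells. Macrophage RNA was not confined to it. A cycling cluster of 1738 cells held 24.4%, 26.5% and 25.1% of all C1qa, C1qb and C1qc UMIs, and the macrophage-like cluster 21.2%, 18.0% and 17.8%. The cycling cluster was 8.44% of the pooled cells, at 2.17 times the median UMIs of its wells. The macrophage-like cluster was 1.34% of them, at 0.75 times, so it was far richer in these genes per UMI. Whole macrophages that passed the sort are argued against by the progenitor genes, since Cd34 in the cluster was at 140.7% of its level in the other cells, Kit at 165.9% and Flt3 at 181.0% (means of 4 wells). Doublets of a whole macrophage with a whole progenitor stay open. The macrophage-like cluster had 0.763 times the median UMIs of the other cells (0.70 to 0.885 per well), but these include the deep cycling cells (median 20734). Its median of 10357 UMIs was not below the 9697 of HSC-like cells, so depth does not decide. Free RNA is argued against by C1qa and C1qb over all cells, not this cluster alone. They were found together in 13.7 times as many cells as independent draws give (7.60 to 17.0 per well). Macrophage fragments bound to progenitors may be a candidate source and stay open, as no value here tests them, and no biological explanation was tested because the design has 1 group.

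Of 424 sets of 4 wells 21 had a highest or lowest well far from the others by Dixon's test, and chance alone flags about 1 in 20. The sets overlap, because several rest on the same wells and cells. In well 3 the median CD48 antibody count was 286 per cell, against 218 to 227 in the other wells. The median CD150 count was 1 in well 4 and 2 in the other wells. The remaining values are log2 ratios per well. Between reporter-high and reporter-low cells Dntt was at 5.85 in well 4 (6.58 to 6.70 elsewhere), and this value counts also for the hCD4 antibody and its target. In the same comparison Car1 was at −4.69 in well 1 (−5.64 to −5.51 elsewhere), Itga2b at −4.42 in well 3 (−3.91 to −3.89) and Cebpa at 1.04 in well 4 (1.44 to 1.48).

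Between the ESAM gates S100a9 was at −7.25 and S100a8 at −7.23 in well 4, against 0.18 to 0.47 and 0.34 to 0.80 in the other wells. A neutrophil gene cluster of 95 cells held 92.1% of all S100a9 and 91.6% of all S100a8 UMIs. Cst7 was at −0.97 in well 3 (−1.01 elsewhere), Itga2b at 0.66 in well 4 (1.46 to 1.61) and Csf1r at −1.09 in well 1 (−1.35 to −1.31). Between the HSC and MPP4 gates Ctsg was at −1.49 in well 4 (−3.28 to −3.02 elsewhere) and Cxcr4 at −0.98 in well 3 (−0.60 to −0.58). Klf1 was at 3.28 in well 2 between the MPP2 and MPP3 gates (1.90 to 2.01 elsewhere). Between Dntt-positive and Dntt-negative cells Angpt1 was at −0.65 in well 4 (−0.88 to −0.86 elsewhere), Cpa3 at −2.49 in well 1 (−2.04 to −1.98), mt-Cytb at −0.11 in well 2 (−0.04 to −0.03) and Lck at 1.2 in well 4 (1.5 to 1.56). Between cells high and low for the CD41 antibody Itga2b was at 3.23 in well 4 (3.88 to 4.00 elsewhere).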

How the results depend on the processing

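Chosen only after the results were seen were the YFP comparison and the tests with log antibody counts not centred, the highest doublet scores left out, the macrophage-like, T/NK-like and neutrophil gene clusters left out, ESAM gates at the same reporter level, and HSC-like or primed cells left out. The reporter and the HSC comparisons stayed within 1.5 times their counts of calls under every setting run (4530 to 6585 and 4035 to 6190), and without each well they gave 5677 to 6168 and 5015 to 5284. The ESAM comparison gave 3400 to 4136 calls without each well, MPP2 against MPP3 187 to 559, Dntt mRNA 2765 to 3157 and YFP 194 to 540. Scaling moved the median log2 fold change of all genes by under 0.1 in every comparison. The cause of each change below was not tested.

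The pairing by well is part of the design. Without this block 2384 genes were called between the ESAM gates (4402 with it), 96 between MPP2 and MPP3 (615), 1916 for Dntt mRNA (3534) and 193 for YFP (443), and the other 2 counts stayed within 1.5 times. DESeq2 with the well as a term called 2063, 159, 1866 and 128 genes in the same order. Of the ESAM calls 36.4% were higher under DESeq2 and 48.3% under edgeR, and of the YFP calls 73.4% and 62.3%. Cells thinned to 5000 UMIs gave 1548 calls for ESAM (1502 shared) and 135 for MPP2 against MPP3, and Dntt mRNA at 3000 UMIs gave 2302. These fits hold fewer UMIs. Leaving out cells scored S or G2/M gave 1207 calls for ESAM (1107 shared) and 47 for MPP2 against MPP3, and narrower gates 235 (224 shared) and 1. Antibody counts divided by their total gave 2415 calls between MPP2 and MPP3 and Gaussian mixture gates 3863. Log counts without centring gave 2860 there and 2280 for ESAM, and ESAM gates at the same reporter level 2876.

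Of 70 tests of gene lists 49 were called, 18 with an estimated correlation, 46 with fry and 47 to 53 without each well. All 11 antibody targets were called, and 10 under some settings. Fry ended the calls of G2 and M phase (adjusted p = 0.0513) and immediate early genes (adjusted p = 0.0706) for the reporter, of G2 and M phase genes for HSC against MPP4 (adjusted p = 0.0588), of mast, S phase (adjusted p = 0.0880 each) and G2 and M phase genes (adjusted p = 0.285) for MPP2, and of neutrophil (adjusted p = 0.0582) and immediate early genes (adjusted p = 0.0947) for Dntt mRNA. It called macrophage (adjusted p = 0.0179 and 0.0227) and endothelial genes (adjusted p = 0.0181 and 0.00576) for the reporter and HSC comparisons and endothelial genes for Dntt mRNA (adjusted p = 0.0154). For YFP it ended 6 of 7 calls, those of the stem cell, erythroid, neutrophil and monocyte, dendritic, S phase and G2 and M phase lists.

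The HSC-like share of 14.1% was 23.6% at resolution 0.5, 9.64% at 1.2, 9.57% with the highest doublet scores left out and 14.7% to 24.2% without each well. The lymphoid-primed-like share of 11.7% was 16.3% at resolution 0.5, 25.1% without cell cycle genes, 8.26% without the highest doublet scores and 5.45% to 16.7% without each well. Megakaryocyte-primed-like cells were 3.92% to 8.57%, erythroid-primed-like cells 1.57% to 3.01% and macrophage-like cells 0.377% to 1.48% without each well, and macrophage-like cells 2.13% without the highest doublet scores. No lymphoid cluster was found at resolution 1.2. No macrophage cluster was found at resolutions 0.5 and 1.2, with cell cycle genes left out, or without well 3 or 4. Keeping the called doublets is void as an alternative, since none was removed.

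Some named genes reversed, with the log2 fold changes given here. With antibody counts divided by their total these were Aurkb (−0.066) for the reporter and Cxcr4 (−0.58) as an antibody target. Between MPP2 and MPP3 they were Elane (−0.57), Hlf (0.15), Procr (0.0087), Tyms (−0.059), Dut (−0.077), Uhrf1 (−0.047), Birc5 (−0.035), Aurkb (−0.091) and Eng (0.071). Mixture gates turned Elane (−4.26). Without centring C1qb (0.0038) and Vcam1 (0.24) turned for the reporter, Mpo (0.17) and mt-Nd1 (0.0028) for ESAM, and Elane (−1.54), Hlf (0.093), Procr (0.095), Ms4a3 (−0.17), Id2 (−0.0076), Dut (−0.0022), Trbc2 (−0.44) and Eng (0.16) for MPP2. Narrower gates turned Selp (−0.24), Mpo (0.070), Bst2 (0.11), C1qb (−0.066) and Emcn (−0.039) for ESAM, and Klf1 (−0.29), Tyms (−0.18), Dut (−0.17), Cd9 (−0.033), Eng (0.35) and YFP (0.16) for MPP2. At the same reporter level Tcf4 (0.019), Cpa3 (−0.023) and human CD4 (0.14) turned.

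Outside S and G2/M Top2a (0.11), Birc5 (0.099), Cdk1 (0.0023), Jund (−0.010), mt-Nd1 (0.019) and S100a9 (0.13) turned for ESAM, Tpx2 (0.26) for HSC against MPP4, and Mpo (0.020) and Prtn3 (0.062) for MPP2. Since phase was scored from the cell cycle lists, the turns of their members are no separate result. In thinned cells C1qb (−0.22) turned for ESAM. Without the macrophage-like, T/NK-like and neutrophil gene clusters S100a9 (0.34) and S100a8 (0.73) turned for ESAM, and Elane (−0.42) and Id2 (−0.017) for MPP2. Without each well in turn S100a9 ran from −6.26 to 0.39 and S100a8 from −6.27 to 0.88 for ESAM, turning without well 4. Without well 3 Csf1r (0.031) turned for MPP2 and Slamf1 for YFP (from −0.66 to 0.25 without each well). Lists without a call that changed direction were mast genes for HSC without wells 1, 2 and 3 (adjusted p = 0.961, 0.821 and 0.976, and 0.796 without well 4), and for MPP2 stem cell genes without well 3 (adjusted p = 0.918, and as low as 0.0127 without well 4). Without well 4 neutrophil (adjusted p = 0.575), interferon (adjusted p = 0.772) and immediate early genes (adjusted p = 0.511) turned for MPP2. Over the wells left out the first ran from an adjusted p of 0.217 to 0.648 and the second from 0.0941 to 0.794. For YFP they were interferon (adjusted p = 0.270 and 0.846) and immediate early genes (adjusted p = 0.869 and 0.720) without wells 1 and 2, mitochondrial genes without well 2 (adjusted p = 0.769) and antibody targets without well 3 (adjusted p = 0.661, and up to 0.986 without other wells).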

Other observations

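The YFP comparison, its alternatives, the tests on erythroid-primed-like cells and the ESAM settings at the same reporter level and without HSC-like cells were chosen only after the results were seen.

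Among the 25% of cells lowest for the hCD4 antibody, cells with a YFP UMI had higher mast, basophil and eosinophil genes than cells without one. Neutrophil and monocyte genes were higher too, without a call by fry (adjusted p = 0.0668). Erythroid and cell cycle genes were higher and stem cell genes lower, but these lists were called neither with an estimated correlation (adjusted p = 0.0956 each) nor by fry. The largest rises under the rule for named genes were Ctsg, cathepsin G (2.23 ± 0.16), Car1 (1.92 ± 0.13), Cpa3 (1.62 ± 0.14), Clec4d (1.53 ± 0.18) and Mpo (1.24 ± 0.10). Ctsg and Mpo were also among the markers of the neutrophil gene cluster of 95 cells. That cluster had a median of 13.1 ± 6.14 hCD4 antibody UMIs, and at 5000 UMIs a YFP UMI in 50.9% ± 16.8 of its cells. Its share of the 2 groups was not counted, and no YFP fit left it out. The largest falls under that rule were Mmrn1 (−1.22 ± 0.17), Ccdc112 (−1.21 ± 0.19), Itsn1 (−1.14 ± 0.19), the lymphotoxin gene Ltb (−1.10 ± 0.10), Procr (−0.96 ± 0.17) and Esam (−0.94 ± 0.18). Of 10539 genes 443 were called by edgeR, 276 higher and 167 lower, with 52 and 46 by at least 2-fold. This rested on 486 cells with and 4452 without a YFP UMI, all thinned to 5000 UMIs, whose medians before thinning were 16802 and 12561 UMIs. The count was 216, 198 and 194 without wells 1, 3 and 4, 128 with DESeq2 and 193 without the pairing by well.

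In that comparison neutrophil and monocyte genes rose in 5 of 12 (6 adjusted over the list alone, median 0.60, camera adjusted p = 6.5e-14) and mast, basophil and eosinophil genes in 4 of 5 (median 2.07, adjusted p = 5.4e-18), both called with an estimated correlation (adjusted p = 0.0264 each) and the second by fry (adjusted p = 0.0477). Stem cell genes fell in 10 of 21 (16 adjusted over the list alone, median −0.75, adjusted p = 3.7e-23), erythroid genes rose in 7 of 13 (8 adjusted over the list alone, median 0.72, adjusted p = 2.6e-15), S phase genes in 9 of 20 (16 adjusted over the list alone, adjusted p = 5.8e-16) and G2 and M phase genes in 8 of 20 (13 adjusted over the list alone, adjusted p = 2.2e-15). With fry the stem cell, S phase and G2 and M phase lists gave an adjusted p = 0.0816 each and the erythroid list an adjusted p = 0.157. Dendritic genes fell in 3 and rose in 1 of 10 (adjusted p = 0.0178, with adjusted p = 0.324 with an estimated correlation and adjusted p = 0.204 with fry), a call that ended without well 2 (adjusted p = 0.0523) or well 4 (adjusted p = 0.179). Not called were megakaryocyte (1 up and 2 down of 11, 2 and 2 adjusted over the list alone, adjusted p = 0.211, but 0.0267 without well 1), lymphoid (2 up of 11, 2 up and 2 down adjusted over the list alone, adjusted p = 0.239), interferon (2 up and 1 down of 15, adjusted p = 0.861), antibody target (1 up and 1 down of 9, adjusted p = 0.861) and mitochondrial genes (0 of 9, 1 up adjusted over the list alone, adjusted p = 0.665). The immediate early list had 4 up and 1 down of 14 (4 and 4 adjusted over the list alone, median −0.14 and mean 0.07 with camera up, adjusted p = 0.510). Too few to test were endothelial genes (2 of 4 down), mature neutrophil genes (0 of 2, 1 down adjusted over the list alone) and the 1 tested gene each of the mature B cell, T and NK cell and macrophage lists (0 passed).

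Other clusters stood outside the named types. A cluster of 207 cells, 0.982% ± 0.227 of the cells, was led by interferon response genes (Ifit3, Cxcl10, Mx1, Ifit1 and Rsad2), and 95 cells, 0.455% ± 0.184, by neutrophil genes (Camp, S100a9, S100a8, Ngp and Elane). A cluster of 203 cells had a median of 3185 UMIs, 0.241 times that of its wells. Across antibodies, CD55-high cells carried higher erythroid genes (14 of 16, median 5.53), megakaryocyte genes (11 of 11, median 4.62) and stem cell genes (22 of 22, median 2.21). CD9-high cells carried higher stem cell (22 of 22, median 1.36) and megakaryocyte genes (11 of 11, median 2.38), but 8 of 16 erythroid genes were lower and 4 higher. CD105-high cells had 14 of 16 erythroid genes higher (median 1.69) and 7 of 11 megakaryocyte genes lower.

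YFP transcript was at 163 ± 11 CPM in erythroid-primed-like cells, whose Dntt was at 4.53 ± 3.99 CPM, while HSC-like cells had 44.2 ± 3.11 and 10.5 ± 3.13 CPM. At 5000 UMIs a YFP UMI was found in 36.2% ± 9.52 of erythroid-primed-like and 10.3% ± 1.02 of HSC-like cells (48.5% and 19.8% before thinning, medians 19673 and 9697 UMIs, 13 and 75 shallower cells left out). Free RNA or doublets with reporter-positive cells would bring Dntt along with YFP. The ratio of YFP to Dntt was 19.0 times that over all cells (8.77 to 33.2 per well, with a floor of 3 Dntt counts in well 3, where Dntt was 0). Dntt was at 4.15% of the level the YFP excess would need from such doublets (0% to 8.06%). Both values restate the pattern that prompted them, so they do not decide on either cause. Transcription at the locus at the time of capture is argued against as the whole cause by the hCD4 antibody. Its median was 11 ± 6.22 UMIs in erythroid-primed-like and 9.5 ± 5.20 in HSC-like cells, against 384 ± 79.2 in lymphoid-primed-like cells (SD). Medians leave activity in a minority of the erythroid-primed-like cells open. YFP at 3.70 times that of HSC-like cells (3.45 to 4.01) with less Dntt in every well is the pattern itself and no separate test. Activity of the locus in an ancestor may explain the YFP in these cells, as may recombination that did not need such activity, and neither was tested.

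Stem cell genes were higher in ESAM-high than in ESAM-low cells of the reporter-positive MPP4 gate (median log2 fold change 0.82). A lower reporter level in the ESAM-high gate is argued against as the whole cause by the median of 0.58 with gates at the same level, though the call then had an adjusted p = 0.0567 with an estimated correlation. The cells of the HSC-like cluster are argued against as the whole cause by the median of 0.76 without them (15 of 17 up). That cluster was only 2.92% of the ESAM-high gate, so stem-like cells outside it stay open. Unnamed cells made up 40.4% ± 2.54 of the ESAM-high and 12.1% ± 3.30 of the ESAM-low gate. Fewer cycling cells are argued against as the whole cause by the median of 0.67 outside S and G2/M (11 of 15 up). The larger share of lymphoid-primed-like cells in the ESAM-low gate may contribute and was not tested, and with 1 group in the design no difference between groups of animals was tested.

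Other splits of the 8 libraries of each comparison into 4 and 4 were fitted without the pairing by well. As many calls as the real split came from 1 of the 35 splits, the real one, for the reporter (4927 calls, highest other 1), ESAM (2384, highest other 3), HSC against MPP4 (4035, highest other 2), MPP2 against MPP3 (96, highest other 17), Dntt mRNA (1916, highest other 4) and YFP (193, highest other 8). The same was found for antibody targets (10, highest other 0). This fit ignores that the libraries are paired by animal and so cannot be exchanged freely, so these splits do not exclude chance. For the gene lists 2 of the 35 splits gave as many calls (46 in the real one and 46 in the highest other), so chance cannot be excluded for that count either. With the pairing kept, only 8 splits part all the pairs, too few for a share under 0.05, so in the paired fit that the report uses the splits do not decide. Their highest other counts were 0 for the reporter, ESAM, HSC and Dntt mRNA (6527, 4402, 5809 and 3534 in the real split), 1 for MPP2 (615) and 38 for YFP (443). Gene lists were counted only in the fit without the pairing. There the other splits that part all the pairs gave at most 41 (46 in the real split).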
